A study of Zea mays with 2 samples.

How the data were processed

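Nascent RNA was measured by global nuclear run-on sequencing (GRO-seq), in which nuclei extend transcripts already in progress with a bromouridine label and the labelled RNA is captured with an antibody and sequenced. The maize seedlings carried the B73 background per the labels, were homozygous for an rpd1 mutation or for the wild-type allele, and were harvested on day 8. The rpd1 gene encodes the catalytic subunit of RNA polymerase IV, a plant polymerase that makes precursors of small RNAs. Nuclei from the above-ground shoots of 10 seedlings were pooled for each genotype, and each pool gave 1 library. Both libraries were assigned to their genotype from the labels.

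The authors deposited 4 tables of raw read counts, for genes and for annotated transposable elements (TEs), each on the sense and on the antisense strand of the feature. Bowtie 0.12.7, bedtools and DESeq are named in the submitters' processing notes, with no role or order. The genome build, the annotation release and the treatment of reads with several equally good positions are not given in the sources used here. That last point matters for repeats, because reads of near-identical copies can be dropped, split or placed at random. The deposited counts are whole numbers, and 39656 genes and 1612638 TE entries were listed. TE entries overlap each other, so 1 read can count in several of them. The entries left after removing overlaps held 82.2% of the sense and 80.6% of the antisense TE reads.

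The authors also deposited 4 tables of features that differed between the libraries. Their columns hold a normalised mean for each library, a fold change as the ratio of rpd1 to wild type, its log2 value, a p-value and an adjusted p-value, per the file headers. The column names are those of DESeq. The authors' normalised means equalled the sense gene counts divided by size factors of 1.02 for wild type and 0.977 for rpd1. The authors' size factors were 1 for the antisense gene table and both TE tables. No replicate supports these p-values, and they were used only as the authors' values.

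Counts were put on 1 scale with the median-of-ratios size factors of the sense gene counts, which set the rpd1 library at 0.955 of the wild-type depth. The same pair of factors was used for all 4 tables. Each ratio is rpd1 over wild type, with an exact conditional binomial (Clopper-Pearson) 95% interval. With 1 library per genotype there is no replicate error, no test between genotypes and no p-value of this work. Intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules, and they compare these 2 libraries, not the genotypes. For summed TE entries that overlap, the intervals are also too narrow, because some reads count more than once. A feature was past the fold rule when it had at least 20 reads in both libraries together, a ratio of at least 2 or at most 0.5, and an interval that excluded 1. For a feature with 0 reads in a library no ratio is given, only its counts or the bound of this interval.

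The fold rule was tested on simulated Poisson counts, which hold counting error alone and leave out differences between pools and between library preparations. With no difference between libraries, 49 sense genes were past the rule as higher and 62 as lower, among 23795 assessed. The same simulation gave 59 and 70 for antisense genes, 174 and 152 for sense TE entries, and 164 and 162 for antisense TE entries. In simulated sense genes, 52% of 200 genes seeded with a ratio of 2 were recovered and 96% of those seeded with a ratio of 3. For antisense TE entries the recovered shares were 43% and 76%.

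Gene names came from a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0, used only for names. It matched 18774 of the 39656 gene identifiers (47.3%), and 2493 of them had a usable symbol or alias. Aliases can be shared by unrelated genes, so lists drawn up from them can hold such genes, and near-identical family members were read as uncertain. Such lists can also miss genes known by other aliases. No identifier was paired with the symbol rpd1, so the targeted gene was not analysed here and the labels were not checked by it.

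Gene lists were summarised by the number of members past the rule and by the median log2 ratio, computed with 0.5 added to each count. That median was placed among 10000 random lists of the same size matched on read number, as a description of these libraries. A simulated shift of a list of 15 genes was recovered at percentile 0. That shift was larger than the median of any list fixed in advance or added, so it says nothing about smaller shifts. Before the data were examined, 8 lists of symbols were fixed, while 24 lists, drawn up from the aliases, were added after the data had been opened and were not fixed in advance. Another 15 lists, set by gene description, were not run because the reference holds no descriptions. Lists with fewer than 5 assessed members were not summarised.

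Named features followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest named sense genes past the fold rule with at least 50 reads in the higher library, and the 8 highest and 8 lowest antisense genes with at least 30 reads. It took the 5 highest and 5 lowest TE entries per strand with at least 50 reads, and the 5 highest and 5 lowest TE families with at least 1000 reads. It also took up to 4 members of each list fixed in advance, those with the most reads, the 5 largest changes per direction in the authors' deposited tables, and at most 2 unnamed identifiers per direction. Other features are said to have been chosen after their values were seen.

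Alternatives were TMM scaling, total reads of the 4 tables, size factors of each table itself, a minimum of 1 or 100 reads, a ratio of at least 4, a 99.9% interval, sums without the 10 entries with the most reads, and copy medians. TE entries without overlaps and TE entries without a part of chromosome 1 were added after seeing the data, as were all scalings of the summed TE ratios and own-table factors for superfamilies. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for the TMM factors.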

Results

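Nascent transcription was compared between wild-type and rpd1 mutant maize shoots to ask what RNA polymerase IV contributes to the transcription of genes and repeats. Each genotype had 1 library made from the pooled nuclei of 10 seedlings, so no value below has replicate error. The wild-type library held 9877340 reads over the 4 tables and the rpd1 library 9288356. Sense gene reads made up 75.3% of the wild-type total (7436066 reads) and 74.0% of the rpd1 total (6877802 reads). Antisense gene reads made up 6.57% and 6.91%, sense TE reads 8.95% and 9.33%, and antisense TE reads 9.19% and 9.71%. The exact binomial intervals of these shares were narrower than the gaps between the libraries, but they cover counting error only.

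More genes were lower than higher in sense transcription in the rpd1 library by the fold rule. Of 23811 genes with enough reads, 251 were past the fold rule as higher in rpd1 and 502 as lower. Counting error alone gave 49 and 62 in simulated counts, which leave out any difference between separate pools of seedlings. Among named genes with at least 50 reads in the higher library, those with the lowest ratios included pep1, the phosphoenolpyruvate carboxylase of C4 photosynthesis, with 1099 reads in wild type and 320 in rpd1, a ratio of 0.305 (95% counting interval 0.268 to 0.346). ME1 (also me3), the NADP-malic enzyme of the same cycle, went from 971 to 324 reads, a ratio of 0.350 (0.307 to 0.397). The cytokinin gene ciszog1, a cis-zeatin O-glucosyltransferase, had the lowest ratio of any named gene with that many reads, 0.254 (0.168 to 0.374). It was followed by MYB164 at 0.294, a MYB transcription factor gene, and pep1.

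The other named genes of the lower set were Natterin-4 at 0.328, MYB63 at 0.346, Myb5 at 0.349, aux2 at 0.366, Laccase-13 at 0.374, gl4a at 0.374, sdh1 at 0.403 and gst13 at 0.404. Natterin-4 had the most wild-type reads of these, 1547 against 484 in rpd1, with no correction for gene length. Of the 33 named genes with that many reads that met the rule as lower, these 12 had the lowest ratios. Among named genes with that many reads 5 met it as higher. They were m26 with 30 reads in wild type and 86 in rpd1 (interval of the ratio 1.96 to 4.72), the ethylene response factor gene ERF1 with 2.55 (1.98 to 3.30), sfp6 with 2.51, gar1 with 2.49 and P4H4 with 2.01. Unnamed genes had larger ratios: GRMZM5G866269 had 4 reads in wild type and 62 in rpd1, and GRMZM2G143082 had 13 and 156. In the other direction, GRMZM2G072298 had 169 and 19 reads and GRMZM2G337190 had 166 and 22. With a ratio of at least 4 the numbers were near even, 46 higher and 51 lower, while with at least 100 reads they were 65 and 204 and with a stricter confidence level 123 and 298.

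Genes of photosynthesis were lower as groups in the rpd1 library. Of the 10 assessed members of the C4 cycle and carbon fixation list fixed in advance, 4 were past the rule as lower, 0 as higher, and all 10 had a ratio below 1. The median log2 ratio was -0.66, at percentile 0 of matched random lists. Its members with the most reads were the pyruvate phosphate dikinase gene ppdk1 (5600 reads in wild type and 3106 in rpd1, ratio 0.581), mdh4 (1911 and 1622, ratio 0.889), ssu1 of the Rubisco small subunit (1244 and 819, ratio 0.690) and pep1. Those past the rule were pep1, ME1, the NADP-malate dehydrogenase gene mdh6 at 0.495 and the Rubisco activase gene rca1 at 0.473, of which mdh6 and rca1 were chosen after their values were seen. The 3 members matched only through the shared symbols PDK1 and Pep1 may be other genes. Without them 4 of 7 were lower and the median log2 ratio was -1.01, again at percentile 0. Those 7 still held mdh4, whose alias CYTMDH points to a cytosolic enzyme that may lie outside the cycle. A wider C4 list, not fixed in advance, of 19 assessed genes held 7 that were lower and 0 that were higher, and 16 had a ratio below 1. Its median log2 ratio was -0.51 at percentile 0. It holds the same 10 genes again, so it is not separate support. The near-identical Rubisco small subunit genes can share reads.

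The light harvesting and photosystem list, not fixed in advance, lay on the same side. All 20 assessed members had a ratio below 1, 5 of them past the rule, and the median log2 ratio was -0.66, at percentile 0. The 5, chosen after their values were seen, were the antenna genes lhcb6 (284 reads in wild type and 115 in rpd1, ratio 0.424), lhcb4 (470 and 218, ratio 0.486) and cab48 (26 and 6, ratio 0.242), the photoprotection gene psbs1 (711 and 324, ratio 0.477) and the ferredoxin gene fdx2 (43 and 17, ratio 0.414).

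**Figure D1:**
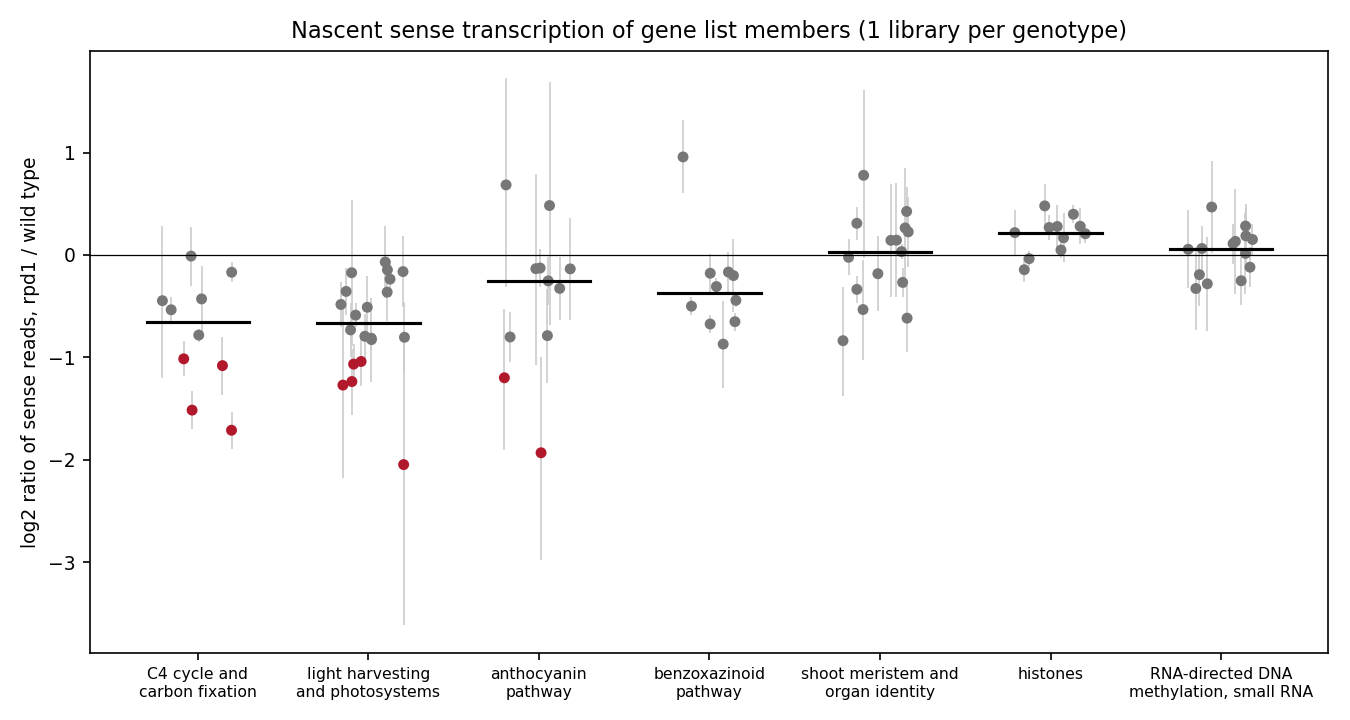
The vertical axis gives the log2 ratio of sense reads (rpd1 over wild type) of each assessed member of 7 gene lists, with 95% counting intervals as grey lines, list medians as black bars and members past the fold rule as lower in red. Members of the C4 and light harvesting lists lie at or below 0 with medians of -0.66. Histone genes centre at 0.22 and the list of RNA-directed DNA methylation and other small RNA genes at 0.06.

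Pigment and defence pathways held fewer or no genes past the rule. In the anthocyanin list fixed in advance, 2 of 11 assessed genes were lower and 0 higher, with a median log2 ratio of -0.25 at percentile 4.38. These 2 were A1, which encodes dihydroflavonol reductase (48 reads in wild type and 12 in rpd1, ratio 0.262), and f3h, the flavanone 3-hydroxylase gene (65 and 27, ratio 0.435), both chosen after their values were seen. The members with the most reads were the pac1 pair, with ratios of 0.915 and 0.839, the chalcone synthase gene c2 with 0.574 and the regulator r1 with 0.797. The wider anthocyanin list of 12 held the same count of 2 lower genes, with a median log2 ratio of -0.19 at percentile 6.3. Benzoxazinoid genes, which make a grass defence compound, had 0 of 10 members past the rule, but 9 of 10 had a ratio below 1 and the median log2 ratio was -0.38 at percentile 0.07. In that list, as genes chosen after their values were seen, bx1 had 2760 reads in wild type and 1862 in rpd1, and BX14 went the other way, with 102 and 189. The jasmonate and oxylipin list had 0 of 44 past the rule, 37 with a ratio below 1 and a median log2 ratio of -0.22 at percentile 0.

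Genes of small RNA pathways, DNA methylation and chromatin showed no member past the rule. Of 14 assessed genes of RNA-directed DNA methylation and small RNA pathways, 0 were past the rule, and the median log2 ratio was 0.06 at percentile 77.58. This list also holds genes of other small RNA pathways, so its median is not that of the RNA polymerase IV pathway alone. A ratio below 1 was seen in 5 of the 14, including the 3 genes named next. The list fixed in advance had only 3 assessed members: rmr7, a shared subunit of RNA polymerases IV and V, with a ratio of 0.920 (469 reads in wild type, 412 in rpd1), mop1, an RNA-dependent RNA polymerase, with 0.797 (121 and 92), and rmr2 with 0.822 (93 and 73). The 16 genes of DNA methylation and methyl-binding (median log2 ratio 0.07, percentile 87.19) and the 37 chromatin modifiers (0.03, percentile 72.05) also had 0 members past the rule. Of the 4 DNA methylation genes assessed from the list fixed in advance, met2 had a ratio of 1.04, met5 of 0.966, dmt106 of 1.17 and dmt101 of 1.12.

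Histone genes were the list with the highest percentile, 99.96, with a median log2 ratio of 0.22, 9 of 11 members above 1 and 0 past the rule. Several of them have near-identical copies, which leaves their separate values uncertain. The 15 shoot meristem and organ identity genes had 0 members past the rule and a median log2 ratio of 0.03 at percentile 71.33, although their mean was -0.03. Their members with the most reads were ts1 with a ratio of 1.02, rs2 with 0.792, knox8 with 0.830 and rld1 with 1.24. Of the HD-ZIP IV genes, which mark the outer cell layer, ocl3 had a ratio of 1.05, ocl1 of 0.968, ocl4 of 1.22 and ocl5 of 1.14. The circadian clock list had 1 assessed member, PRR59, with a ratio of 1.13. The organelle list matched 4 genes by alias, which may be nuclear relatives: ATPB with a ratio of 0.899, atp1 with 1.04, rps12 with 0.977 and nad1 with 1.09.

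Housekeeping, hormone and transport lists held at most 1 gene past the rule in each direction. Lists with 0 members past the rule were ribosomal proteins (34 genes, median log2 ratio -0.03), homeobox (37, 0.01), MADS box (18, 0.01), SBP box (21, -0.01), expansins and cell wall (33, -0.04), tubulins and actins (21, -0.09) and cell cycle and replication (27, 0.03). Their percentiles ran from 18.04 for tubulins and actins to 64.71 for the cell cycle. Lists drawn up from aliases can miss genes. The MADS box list did not hold m26, whose alias resembles those of its members m19 and m27, so the 0 covers listed members only. Likewise, the cytokinin response list did not hold ciszog1. The auxin response list had 1 of 47 higher and 1 lower (median 0.03, percentile 82.05), and the cytokinin response list 1 of 23 lower (median -0.12, percentile 5.43). Heat shock and chaperone genes had 1 of 22 lower (median -0.06, percentile 27.66), which was HSP90-1 at a ratio of 0.474, named after its value was seen. Phosphate and metal transport had 1 of 26 lower (median -0.07, percentile 20.53) and aquaporins 1 of 22 lower (median -0.21, percentile 1.02). The pathogen and wound response list had 1 of 30 higher and 1 lower (median 0.08, percentile 96.33, mean -0.02). The list meant for embryo genes had 1 of 10 higher (median 0.12, percentile 85.3), but by their aliases it held a hemoglobin gene, the floral gene zfl1 and genes with embryo-defective names, so it does not measure embryo tissue. The list meant for endosperm genes had 3 assessed members, which may be other genes of the same alias, with ratios of 1.39 for MRP1, 1.02 for Floury1 and 1.65 for zp15, all named after their values were seen. The single members past the rule, named after their values were seen, were PIN9 (2.27) and aux2 (0.366) for auxin, cko3 (0.331) for cytokinin, NRT1.2 (0.228) for transport and Lsi6 (0.489) for aquaporins. They were PR10 (2.10) and tps26 (0.488) for pathogen and wound response and an oleosin gene (2.42) for the list meant for embryo genes. The means of the homeobox, SBP box and auxin lists also differed in sign from their medians and were -0.02, 0.01 and -0.04.

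Antisense transcription over genes differed in both directions. Of 7786 assessed genes, 285 were higher and 271 lower in rpd1, where counting error alone gave 59 and 70 in simulated counts that leave out differences between pools. Among named genes with at least 30 antisense reads in the higher library, those with the highest ratios were m26 at 3.46 (10 reads in wild type and 33 in rpd1), FHA17 at 3.04, MSRB1 at 2.74, WRKY96 at 2.43, glossy2 at 2.39 and MYB166 at 2.03. The lowest were LOS4 at 0.257 (57 and 14), TMT at 0.299, aldh5 at 0.358, hsp18 at 0.390, ub2 at 0.426, bx9 at 0.484, nuc at 0.491 and Bm6 at 0.493. Antisense reads from 2 unnamed loci differed more: GRMZM2G421579 had 9 in wild type and 161 in rpd1, and AC234203.1_FG009 had 36 and 0, a ratio of at most 0.113 by its counting interval. The antisense share of gene reads was 8.03% in wild type (exact interval 8.01 to 8.05) and 8.53% in rpd1 (8.51 to 8.55). Reads of an overlapping neighbour on the other strand count as antisense. The balance depended on the setting, with 66 higher and 21 lower with at least 100 reads, and 142 and 72 with a stricter confidence level. The size factors of the antisense table itself gave 240 and 336, but in simulated counts such factors missed the depth difference.

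Changes in the same direction on the sense and antisense strands of a gene coincided more than separate lists would. Among 6586 genes assessed on both strands, 133 were lower in sense and 237 lower in antisense, and 16 were in both, where independent lists would share 4.79. For higher genes the shared number was 5, where independent lists would share 1.74. The m26 gene was higher on both strands. Opposite directions were shared by 2 genes (higher in sense) and 3 genes (lower in sense), where independent lists would share 1.91 and 4.36. Both strands come from the same 2 libraries.

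Transposable elements, the repeats that RNA polymerase IV is known to keep silent through small RNAs, were more often higher than lower in rpd1. Of 15626 assessed sense entries 850 were higher and 519 lower, and of 16933 antisense entries 914 were higher and 479 lower. Counting error alone gave at most 174 per direction in simulated counts, which leave out differences between pools. The excess depended on the setting. With the size factors of the TE tables themselves it narrowed to 716 higher and 601 lower sense entries and 791 and 597 antisense entries, and without a minimum of reads the numbers were near even, 1693 and 1610 for sense and 1615 and 1498 for antisense. Summed over all elements the difference was small, with ratios of 1.03 for sense and 1.04 for antisense reads. With the factors of the TE tables themselves they fell on the other side of 1, at 0.981 and 0.993. Those factors were 1, as they also were in simulated counts that differed in depth, so they do not correct for depth. By superfamily, the largest sums on the sense strand were 1.07 for Copia (1.07 to 1.08) and 1.07 for Gypsy (1.06 to 1.08) LTR retrotransposons. The other sense ratios lay between 0.983 for CACTA and 1.03 for hAT DNA transposons. On the antisense strand, CACTA stood at 1.19 (1.18 to 1.21), from 52241 reads in wild type and 59543 in rpd1. The rest lay between 0.952 for Tc1-Mariner and 1.06 for hAT. Overlapping entries count some reads more than once, so the intervals of these sums are too narrow. Over entries that do not overlap, a setting chosen after seeing the data, the antisense CACTA ratio lay below its interval but above 1. The median over sense CACTA copies was 1.05, which is the scaled ratio of a copy with equal counts in both libraries. With the factors of the TE tables themselves, sense Copia was 1.03, antisense CACTA 1.14, and several other ratios, such as sense hAT at 0.988, fell on the other side of 1.

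**Figure D2:**
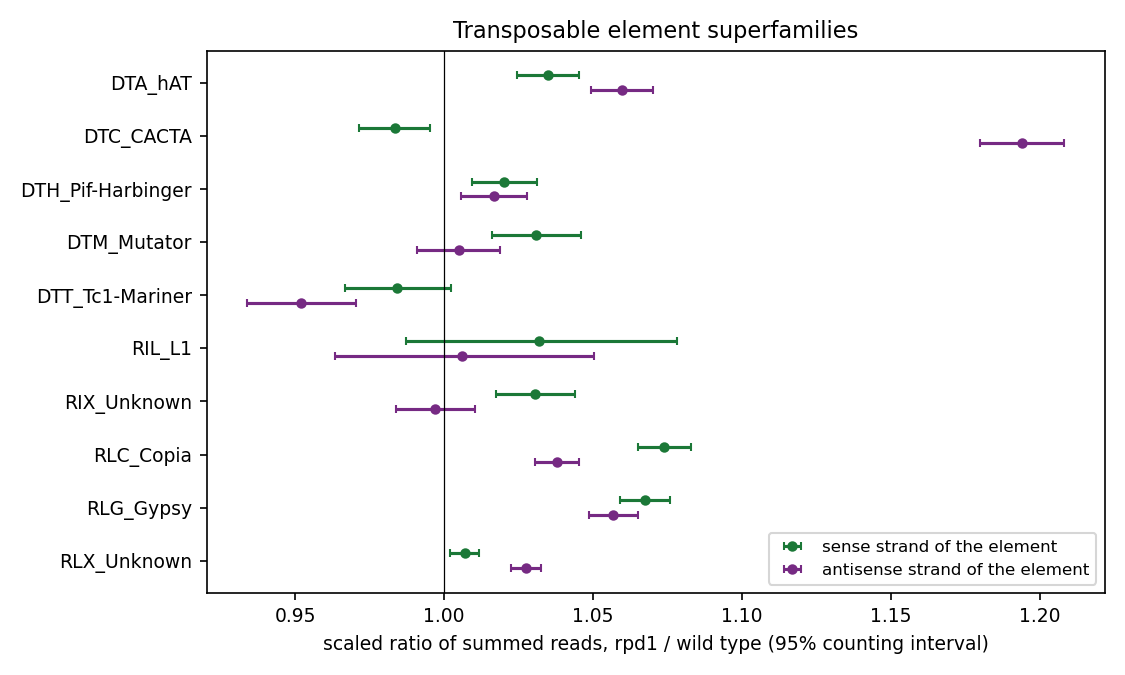
The horizontal axis gives the scaled ratio of summed reads (rpd1 over wild type) for each of the 10 transposable element superfamilies on the vertical axis, with 95% counting intervals as bars, green for sense and purple for antisense reads. Antisense CACTA reads sit apart at 1.19, while the lowest value is antisense Tc1-Mariner at 0.952. Overlapping entries count some reads more than once, so the bars are too narrow.

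Antisense reads of a few CACTA families carried the highest ratios of all families. Among 308 families with at least 1000 antisense reads, ZM_CACTA_noncoding_2 had 2067 reads in wild type and 5258 in rpd1, a ratio of 2.66 (2.53 to 2.81). Of its 50 assessed entries, 47 had a ratio above 1, 31 were past the rule as higher and 0 as lower. Next came ZM_CACTA_noncoding_1 at 2.56, ZM_CACTA_noncoding_7 at 2.35, the Gypsy family nihep at 1.86, with 7 of 11 assessed entries above 1 and a copy median of 1.18, and ZM_CACTA_16 at 1.85 (1.76 to 1.94). The 3 noncoding families share their top locus, on chromosome 3 from 7523756 to 7524580, where overlapping entries held 211 reads in wild type and 893 or 889 in rpd1, so their ratios partly count the same reads. Over entries that do not overlap, a setting chosen after seeing the data, ZM_CACTA_noncoding_7 had a ratio of 1.34 and ZM_CACTA_noncoding_1 of 1.91. Without their 10 entries with the most reads the ratios were 1.52 and 1.30, and 2.07 for ZM_CACTA_noncoding_2. In the same setting nihep had 2.04 and ZM_CACTA_16 had 1.80. On the sense strand ZM_CACTA_noncoding_2 was not higher, with 472 reads in wild type and 373 in rpd1, a ratio of 0.828 with an interval below 1. The lowest antisense families were ZM_CACTA_noncoding_40 at 0.705, with 73.6% of its reads in 1 entry, kise at 0.740, with nearly all of its reads in 1 entry, ZM_CACTA_86 at 0.812, ijij at 0.818 and ZM_Tourist_21 at 0.830.

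**Figure D3:**
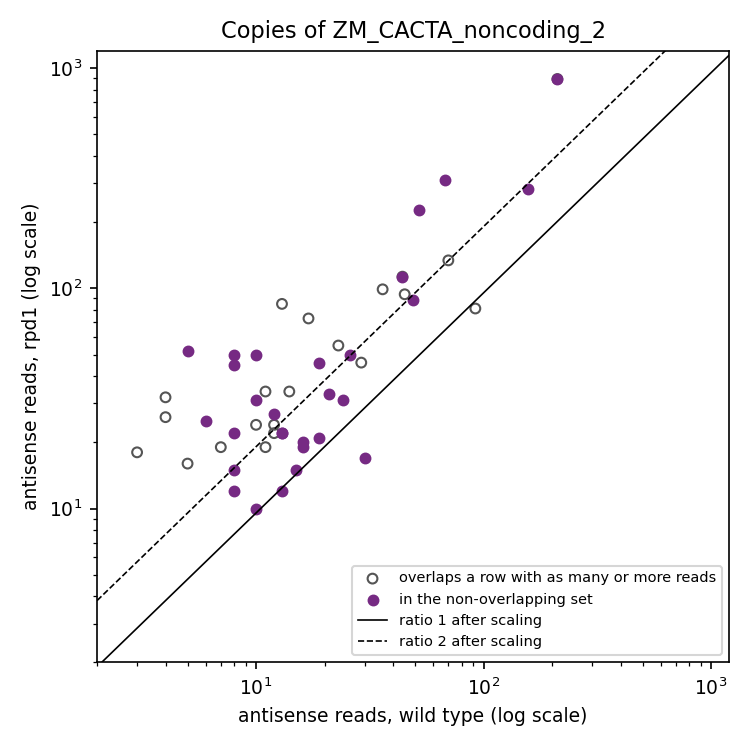
Each point is an annotated copy of ZM_CACTA_noncoding_2 with at least 20 antisense reads, with wild-type reads on the horizontal and rpd1 reads on the vertical axis, both on log scales. Filled points mark copies kept in the set without overlaps, and open points mark copies left out of it because they overlap a kept entry with as many or more reads. Of the 50 copies, 47 lie above the solid line of ratio 1 and the copy with the most reads has 211 in wild type and 893 in rpd1.

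On the sense strand the highest families, among 305, were the Copia family machiavelli with 2964 reads in wild type and 4533 in rpd1 (interval of the ratio 1.53 to 1.68), the Gypsy family flip at 1.59 (1.52 to 1.66), DTM_TAFT1_DQ493649 of the Mutator superfamily at 1.55, uwum at 1.49 and gudyeg at 1.49. The assessed entries did not all share these sums. In uwum 15 of 34 assessed entries had a ratio above 1 and the copy median was 0.914. Above 1 were 16 of 26 in flip, 10 of 19 in gudyeg and 6 of 7 in DTM_TAFT1_DQ493649. Without the 10 entries with the most reads, the ratios stayed at 1.53 in uwum and 1.60 in flip. They were 1.45 in machiavelli, 1.41 in DTM_TAFT1_DQ493649 and 1.31 in gudyeg. Few entries were assessed, 34 of 14285 in uwum and 26 of 32136 in flip, and the sums also hold entries under 20 reads. In machiavelli 51 of 62 assessed entries had a ratio above 1 and 23 were past the rule as higher, with 2 as lower. The lowest sense families were oveah at 0.769, ZM_hAT_23 at 0.791, ZM_hAT_noncoding_17 at 0.807, ojah at 0.832 and ZM_CACTA_34 at 0.832. However, the copy median was 1.08 in ZM_hAT_noncoding_17, and in ZM_CACTA_34 it was 1.05, the scaled ratio of equal counts. Without the 10 entries with the most reads, these 2 families had ratios of 0.882 and 0.747. Ratios of all 305 sense families ran from 0.769 to that of machiavelli.

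Single TE entries showed near-complete differences. Positions are those of the authors' files, whose genome build is not given in the sources used here. Among entries with at least 50 reads in the higher library, the sense entry with the highest ratio was RLG_neha_AC215285_13046, a Gypsy element on chromosome 8 from 143766279 to 143766943, with 2 reads in wild type and 62 in rpd1. Behind it came RLG_fege_AC205532_8884 on chromosome 3 (12 and 132 reads), a ZM_hAT_8 copy on chromosome 5 (5 and 54), RLX_uwum_AC177933_415 on chromosome 2 (23 and 242) and RLC_ufonah_AC194064_3852 (7 and 69). The ufonah entry overlaps the fege entry on chromosome 3, so both can count the same reads. On the antisense strand a ZM_CACTA_34 copy on chromosome 3 from 91408072 to 91408137 had 0 reads in wild type and 50 in rpd1, a ratio of at least 13.7 by its counting interval. RLX_vora_AC206187_9112 had 1 and 108, RLG_dagaf_AC208646_9966 had 3 and 69, a ZM_CACTA_16 copy on chromosome 10 had 4 and 84, and RLG_xilon-diguus_AC195486_4629 had 5 and 88.

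With the same minimum of reads, the 5 entries per strand with the lowest ratios all lay on chromosome 1. A ZM_hAT_8 copy from 187649735 to 187649974 had 97 sense reads in wild type and 0 in rpd1, a ratio of at most 0.0406 by its counting interval. A ZM_Tourist_45 copy from 197059800 to 197059985 had 99 and 7. The other 3 on the sense strand were RIX_ekeje_AC197537-0 with 54 and 10, RLX_naiba_AC195481_139 with 93 and 18 and ZM_PIF/Harbinger_15 with 68 and 14. On the antisense strand RLX_ubat_AC212211_11652 had 119 and 14 and its neighbour RLX_votaed_AC215881_13209 had 106 and 16. RLX_milt_AC209648_10275 accounted for 2 overlapping entries, with 52 and 9 reads and 51 and 9, and RLX_afuv_AC186332_26 had 62 and 12. Summed over chromosome 1 the ratio was 0.978 for sense and 0.972 for antisense TE reads, while the other 9 nuclear chromosomes ran from 0.996 to 1.10 for sense and from 1.03 to 1.08 for antisense.

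**Figure D4:**
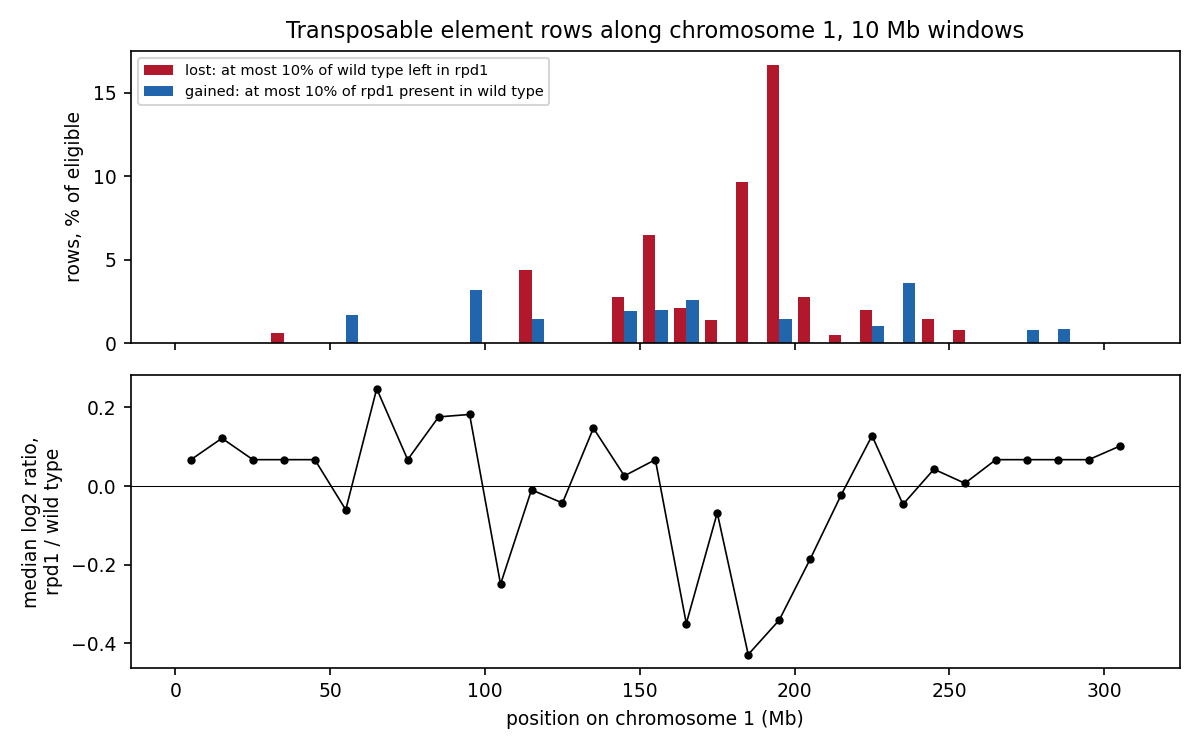
The upper panel gives, for 10 Mb windows of chromosome 1 (position in Mb), the percent of eligible transposable element entries that were lost (red) or gained (blue) in rpd1, where a lost entry had at least 15 reads in wild type and at most 10% of that level in rpd1 and a gained entry the reverse. The lower panel gives the median log2 ratio of assessed entries, and the window from 190 to 200 Mb holds the highest lost share, 16.7%, with a median of -0.34.

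The authors' deposited table for sense genes listed 171 genes, of which 46 were higher and 125 lower in rpd1. The authors' deposited table for antisense genes listed 40, 32 higher and 8 lower, those for TE entries listed 31 on the sense strand (23 higher) and 44 on the antisense strand (31 higher). Of the 171 sense genes 158 were past the fold rule in the same direction, and so were all 40, 31 and 44 of the other authors' deposited tables, as the same 2 libraries lie behind both. In the authors' deposited table, pep1 had a fold change of 0.305 with a DESeq adjusted p of 2.37e-07 and ME1 one of 0.350 with 1.34e-05. GB1 (GRMZM2G062531, which shares this alias with another gene) was among the 5 lowest of the authors' deposited table for sense genes, with 23 reads in wild type and 1 in rpd1. The antisense gene GRMZM2G421579 had a fold change of 17.9 in the authors' deposited table. CACTA entries made up 17 of the 31 higher antisense entries of the authors' deposited table, and Copia entries 8 of the 23 higher sense entries. Overlapping entries share reads, and with overlapping entries of the authors' deposited table counted once, these were 11 of 23 antisense loci and 5 of 18 sense loci. Among the 5 largest changes per direction of the authors' deposited table for sense TE entries were a ZM_hAT_noncoding_120 copy on chromosome 1 with 1 read in wild type and 42 in rpd1, the ZM_hAT_8 copy described above, and 2 overlapping ZM_Tourist_36 entries on chromosome 1 with 31 and 39 reads in wild type and 0 in rpd1.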

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

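TE entries without overlaps, TE entries without chromosome 1 from 100 to 220 Mb, the C4 list without shared symbols, own-table factors for superfamilies and all scalings of the summed TE ratios were alternatives chosen after seeing the data; the rest were planned. No paired analysis was possible because each genotype had 1 library, and no replicate could be left out. The rpd1 ratio alternatives were not run, because no gene identifier was paired with that symbol. All gene list medians and all named genes and TE entries stayed within their main intervals under every alternative run on them. For named genes and TE entries these were scalings only, the largest shift being -0.067 in log2, so this says little about their stability. Each of the counts past the fold rule stayed within 1.5 times its value in the report under TMM, total-read and own-table scaling, and with both added TE alternatives. None of these scalings moved the higher share of such features by over 10 points; own-table factors moved antisense genes most, to 41.7% from 51.3%. Counts depended on the minimum and the size of the change. With at least 100 reads, 65 sense genes were higher and 204 lower, 66 and 21 antisense genes, 71 and 24 sense TE entries, and 111 and 30 antisense TE entries. With a ratio of at least 4 these pairs were 46 and 51, 68 and 47, 176 and 128, and 173 and 104. With a stricter confidence level they were 123 and 298, 142 and 72, 273 and 140, and 336 and 127. With no minimum they were 432 and 591 for antisense genes, 1693 and 1610 for sense TE entries, and 1615 and 1498 for antisense TE entries. Fewer or more features could pass by construction in these settings. The excess of higher over lower TE entries thus narrowed without a minimum, where entries of few reads enter.

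Sense CACTA was 0.983 as a sum, 0.998 with total reads and 1.05 as the median over copies with at least 20 reads. That median is the scaled ratio of a copy with equal counts in both libraries. It was also the median over all assessed sense TE entries. Why the CACTA sum lay lower was not tested. Sense Copia was 1.09 with TMM, 1.09 with total reads, 1.09 as a copy median and 1.07 over entries that do not overlap. Antisense CACTA was 1.21 with total reads, 1.13 without the 10 copies with the most reads, 1.13 as a copy median and 1.12 over entries that do not overlap. Antisense Tc1-Mariner was 0.988 as a copy median. The summed TE ratio was 1.04 for sense and 1.05 for antisense reads with TMM, 1.04 and 1.06 with total reads, and 0.981 and 0.993, on the other side of 1, with own-table factors. Own-table factors gave 0.939 for sense CACTA, 1.03 for sense Copia, 1.14 for antisense CACTA and 0.909 for antisense Tc1-Mariner. They turned sense hAT to 0.988, Pif-Harbinger to 0.974, Mutator to 0.984, the RIX class to 0.984 and the RLX class to 0.961, and antisense Pif-Harbinger to 0.971, Copia to 0.991 and RLX to 0.981, all from ratios whose interval lay above 1. Sense L1 at 0.985, antisense L1 at 0.960 and antisense Mutator at 0.959 also crossed 1, from intervals that included it. These factors are 1 for both TE tables and so undo the depth scaling. Over entries that do not overlap machiavelli was 1.52, and without chromosome 1 from 100 to 220 Mb ijij was 0.920 and oveah 0.895. For these values, too, the cause was not tested. Without the 10 entries with the most reads in each table, the shares of wild-type reads were 75.8% sense gene, 6.17% antisense gene, 8.79% sense TE and 9.22% antisense TE, and those of rpd1 reads 74.5%, 6.56%, 9.19% and 9.74%. The antisense share of gene reads was 7.43% in wild type and 8.00% in rpd1 without the 10 genes with the most antisense reads, by construction lower. Of 1612638 sense TE entries 220256 held any read and 15626 at least 20, and entries under 20 reads were not assessed.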

Other observations

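The tests in this part were all chosen after the results they bear on had been seen. Some genes that the alias lists did not hold were lower too, and the ones named here were chosen after their values were seen. Some may belong to the listed pathways, as psa6 may by its symbol to the photosystems. They therefore do not show a fall beyond photosynthesis. The glycolate oxidase gene go1, of photorespiration, had 793 sense reads in wild type and 329 in rpd1, a ratio of 0.435 (95% counting interval 0.381 to 0.495). LPE1, a leaf permease gene, had 715 and 341 (ratio 0.500), and psa6 had 663 and 300 (ratio 0.474). Amy2 had 353 and 146 (ratio 0.433). Kinase gene bif2, which acts in inflorescence development, was higher, but on 3 and 17 reads (ratio 5.94, interval 1.72 to 31.6).

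Photosynthesis genes were lower as lists in the rpd1 library. Scaling between the libraries is argued against, since the lowest median log2 ratio of 10000 matched random lists was -0.32 and that of the light harvesting list was -0.66. The fall was not limited to mesophyll genes: 5 bundle sheath markers (me3, rca1, the Rubisco small subunit genes and pck2) together had a ratio of 0.621 (0.589 to 0.655). The ratio was 0.527 for 4 mesophyll markers, whose most abundant gene ppdk1 had 5600 and 3106 reads. All 5 bundle sheath markers are members of the C4 lists already found lower, so they do not measure nuclei of either cell type. Whether mesophyll nuclei were fewer could therefore not be tested. A lower share of expanded green tissue in the rpd1 shoots, or a different time or light at harvest, may give the same picture. Neither can be told apart from genotype with 1 pool each. The cell cycle list at percentile 64.71 and the meristem list at 71.33 lay in neither tail. The histone list at 99.96 lay in the upper one, as more dividing tissue would give. It was picked as the highest of 26 lists, with 0 of 11 members past the rule, so it does not decide the question. Loss of RNA polymerase IV stays open and untested.

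TE entries that were nearly silent in rpd1 clustered on chromosome 1. Lost entries had at least 15 wild-type reads and at most 10% of that level in rpd1. Of the 99 lost entries without overlaps, 14 fell between 190 and 200 Mb, while 10000 reassignments put at most 8 in any 10 Mb window. This argues against chance only if entries are lost independently. Overlaps were removed within each strand, so 1 locus can count on both strands, and neighbouring entries may belong to 1 transcript. Of 179 assessed entries without overlaps between 180 and 200 Mb, 74.9% kept a ratio of 0.5 or more. This argues against a full deletion only if their reads came from these positions. Reads of near-identical copies elsewhere could also keep such entries up, as the handling of such reads is not given. A chromosome segment in the rpd1 seedlings that differs in sequence from the B73 reference is a candidate explanation: 13.2% of eligible entries without overlaps in this segment (8.28 to 19.7) were lost against 0.422% elsewhere, and 1 entry was gained there against 20 lost. The segment was set from the same losses, so this remains a hypothesis, and neither a regional effect of the mutation nor a segment inherited with it, which would need the rpd1 gene to lie nearby, could be tested, because no identifier is paired with that symbol. In the authors' deposited table for either strand, 9 of 17 lower TE loci and 2 of 41 higher ones, overlapping entries counted once, lie in this segment. On chromosome 1 as a whole lie 13 of these lower loci and 5 of the higher ones. Losses also occurred outside the segment: over all entries, 4.40% were lost from 110 to 120 Mb and 6.45% from 150 to 160 Mb. Each of these windows had 4 entries lost and 1 gained. Where the lower genes lie was not analysed here.

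Antisense reads on ZM_CACTA_noncoding_2 were higher in rpd1, with a ratio of 2.66. A few copies do not carry this alone, since the ratio was 2.07 (1.92 to 2.23) without the 10 copies with the most reads. Nor do overlapping entries, since over entries that do not overlap it was 2.58 (2.41 to 2.76), with 27 of 29 assessed copies above 1. A general rise of antisense TE reads is argued against by their ratio of 1.04 (1.04 to 1.04). A few transcribed loci whose reads spread over near-identical copies stay open, as the handling of such reads is not given in the sources used here, and an effect of losing RNA polymerase IV stays untested with 1 library per genotype.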
